A study of Mus musculus with 6 samples.

How the data were processed

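Single mouse trophoblast stem cells, the stem cells of the placental lineage kept in culture with FGF4 and TGF-β1, were profiled after both factors had been removed, per the labels. There were 6 libraries, 1 for each of the times 0, 4, 12, 24, 36 and 48 h. The libraries were made by CEL-Seq2, per the labels' protocols, a method that tags the 3' end of each transcript with a cell barcode and a molecular identifier (UMI), amplifies by in vitro transcription and counts each molecule once. The cells of a library came as columns of 1 table each, and a column is called a well here. The description labels put the 0, 36 and 48 h libraries on one flow cell, called the first here, and the 4, 12 and 24 h libraries on another, called the second. The titles give the first flow cell for all 6 libraries, so the 2 kinds of label disagree, and the split by description was kept as a possible batch.

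The deposited values are raw counts of UMIs per gene and well. Per the submitters' processing notes, the authors used Trim Galore 0.6.4, STAR 2.7.6a and UMI-tools 1.0.1 with the mouse build GRCm38.p6. The gene annotation, the step that assigned reads to genes and the choice of barcodes were not given in the sources used here. The tables held 25414 gene rows between them, of which 23672 matched a RefSeq symbol of GRCm38.p6. A numbered suffix marked 283 rows, which took 0.0927% of UMIs and were kept apart. In the 0 h library Gapdh had 95 UMIs beside 14133 for Actb. The tables do not hold unassigned reads, so whether low counts of such genes reflect expression or assignment was not measured. Listed genes without a row (Fabp3, Cldn7, Tpbpb, Rhox6, Rhox9, Psg18, Psg21, Prl3d1, Prl3d2, Prl3d3, Prl3b1, Prl2c2, Prl2c3, Synb, Pou5f1, Ttr, Dcn, Tagln, Msx1, Atad2, Hspa1a, Hspa1b, Dlk1, Meg3 and Rtl1) were not analysed here.

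A well was to be kept with at least 2000 UMIs and at most 25% mitochondrial UMIs. This removed 0 of 2070 wells, since the smallest held 8488 UMIs and the highest mitochondrial share was 5.87%. UMIs were summed over the wells of a library and scaled to CPM, in which the UMIs of each library have the same total. With 1 library per time point there was no test and no p-value. Each library has a single value, so differences between libraries have no replicate check. Log2 ratios had 0.5 added to each UMI sum and carry an exact conditional binomial 95% interval. CPM values carry an exact Poisson interval and shares of wells an exact Clopper-Pearson interval. All intervals cover counting error only. Where a library held 0 UMIs, the limit was 3 counts.

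Before the data were examined, 24 gene lists, 28 key genes, the markers of other cell types, the alternatives and the rule for named genes had been fixed. The rule took the key genes, then the 15 largest and 15 smallest log2 ratios of CPM with 5 CPM added for 48 h against 0 h, with at least 100 UMIs and the same sign for 36 h against 0 h. It took 8 and 8 each for 24 h against 4 h (same sign for 12 h against 4 h) and 4 h against 0 h, leaving out mitochondrial and predicted genes and pseudogenes. It added up to 4 members per list with at least 50 UMIs and the 15 genes with the largest variance relative to the trend at 0 h. A list was summarised by the median log2 ratio of members with at least 20 UMIs. The percentile of that median among 10000 random lists of the same size, matched on mean expression, describes these libraries only. A member counted as higher or lower from 1.5-fold on, a gene in the transcriptome-wide counts from 2-fold on.

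For comparisons between wells, each well was thinned to 15500 UMIs, leaving 323, 280, 320, 310, 307 and 299 wells at 0, 4, 12, 24, 36 and 48 h. Variance over mean was set against the Poisson value of 1 and against a running median over genes of similar mean. Correlations across wells were set beside 1000 shuffles. They describe 1 library each, since wells are not replicates. Wells were clustered with scanpy 1.11.5 (2000 variable genes, 20 principal components, 15 neighbours, Leiden resolution 0.5). No doublet caller was run. The 5% of wells with most UMIs were left out as possible doublets in an alternative.

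The ratio and interval step was tested on simulated data made from these libraries. The simulated sums were Poisson draws, for which the interval is exact, so its coverage was fixed by design. The simulation checks the calculation only and leaves out spread between wells or libraries. For 48 h against 0 h, with 10058 genes, the interval held the true value for 96% of 100 genes changed by 1 log2 unit and for 96% of 100 changed by 2. A list shifted by 1 log2 unit reached percentile 100 and an unshifted one percentile 75.4. In simulated Poisson wells the median variance over mean was 0.996 across 8106 genes. Alternatives covered TMM factors (edgeR 4.0.16) and median of ratios factors (DESeq2 1.42.0), a total without mitochondrial and ribosomal protein genes, other well minimums, equal weight per well, thinning, minimum counts, mean for median, and clustering settings. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3.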

Results

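The series followed mouse trophoblast stem cells through the first 2 days without FGF4 and TGF-β1, with the stated aim of describing how these cells differ from one another. The 6 libraries held 363, 349, 354, 347, 327 and 330 wells at 0, 4, 12, 24, 36 and 48 h. Their totals were 9559114, 8569806, 10135319, 9361486, 9774160 and 9812980 UMIs. Median UMIs per well ran from 23008 at 4 h to 28373.5 at 48 h, and median genes per well from 5909 at 4 h to 6468.5 at 12 h. Each time point had 1 library, so no value below has a replicate error, and intervals in brackets are 95% intervals for counting error only. By one of the labels the 0, 36 and 48 h libraries shared a flow cell and the 4, 12 and 24 h libraries another. Comparisons were therefore read first within a flow cell. The series held no library of cells kept in both factors for the same time, and none of cells that lost a single factor. Withdrawal can therefore not be told apart from time in culture, nor the loss of FGF4 from that of TGF-β1.

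The comparison of 48 h with 0 h asked how the cells looked at the end of the course. Targets of FGF and ERK signalling and regulators of the stem cell state were far lower in the 48 h library, while genes of the ectoplacental cone, the syncytiotrophoblast and the trophectoderm were higher. Of 10058 genes with at least 100 UMIs, 826 were at least 2-fold higher and 745 at least 2-fold lower. Scaling with TMM factors shifted the median of all genes by -0.09 on the log2 scale and turned the balance, with 711 higher and 837 lower; DESeq2 factors gave 734 and 822. These are differences between 2 libraries and not tested differences between conditions.

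In the FGF and ERK response list, 12 of 14 measured members were lower at 48 h, 0 were higher, and the median log2 ratio was -3.72 [-3.91, -3.50], at percentile 0 of random lists. Spry4, which encodes a feedback inhibitor of receptor tyrosine kinase signalling (chromosome 18, 38586247 to 38601347, GRCm38.p6), stood at 257 CPM at 0 h and 1.73 CPM at 48 h, a log2 ratio of -7.17 [-7.99, -6.53]. The ERK phosphatase gene Dusp6 had 27.4 and 0.611 CPM, and the ETS factor gene Etv4 80.0 and 1.43 CPM. The cyclin gene Ccnd1 had 19.4 and 0.917 CPM.

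In the trophoblast stem cell list, 9 of 13 measured members were lower, 1 was higher, and the median was -2.40 [-2.50, -2.05], at percentile 0. Eomes, a T-box factor required in trophoblast stem cells, had 1029 CPM at 0 h and 98.3 CPM at 48 h. Sox2 had 881 CPM at 0 h, with a log2 ratio of -4.42 [-4.57, -4.28]. Esrrb, an orphan nuclear receptor of the stem cell network, had 556 and 52.9 CPM, and Bmp4 482 and 23.8 CPM. Elf5 had 266 and 60.8 CPM. Tfap2c went the other way, with 227 CPM at 0 h and 418 CPM at 48 h. Cdx2, a defining factor of the trophectoderm, had only 42 UMIs at 0 h and 7 at 48 h, so its ratio is poorly measured.

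The syncytiotrophoblast list had a median of 2.52 [2.25, 2.85], at percentile 100, with 7 of 8 measured members higher and 1 lower. Summed per thinned well the difference was smaller, with a mean of 13.2 UMIs at 0 h and 20.7 at 48 h, medians of 13 and 14, and 55.5% [49.7, 61.2] of 48 h wells above the 0 h median. Dlx3, a homeobox factor of the labyrinth, had 0.837 CPM at 0 h and 156 CPM at 48 h, a log2 ratio of 7.46 [6.56, 8.76]. Syna, which encodes the fusion protein syncytin A, had 1.15 and 27.3 CPM. Gcm1, a regulator of syncytiotrophoblast, had 1 UMI and 10 UMIs. The ectoplacental cone and spongiotrophoblast list had a median of 2.41 [2.03, 2.91], at percentile 100, with 7 of 9 members higher and 2 lower. Ascl2 (chromosome 7, 142966822 to 142969264), a bHLH factor of the ectoplacental cone, had 437 CPM at 48 h and a log2 ratio of 5.44 [5.15, 5.75]. Phlda2, an imprinted growth regulator, had 185 and 2228 CPM. Tpbpa, a classical spongiotrophoblast marker, had 0 UMIs at 0 h and 1 UMI at 48 h, so no ratio was measurable.

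In the trophectoderm list, 9 of 13 members were higher, 0 were lower, and the median was 1.27 [0.93, 1.31], at percentile 100. Krt8 and Krt18, the keratin pair of simple epithelia, had 86.3 and 456 CPM at 0 h and 608 and 1097 CPM at 48 h. Gata2, a zinc finger factor of trophoblast, had 13.9 and 537 CPM, and Gata3 203 and 196 CPM. The trophoblast giant cell list had a median of 0.84 [0.42, 1.35], at percentile 99.5, but a mean of -0.07, since its 7 measured members went both ways. Mmp9, a matrix metalloprotease, had 325 and 2.24 CPM, while Cdkn1c, a cyclin-dependent kinase inhibitor, had 118 and 439 CPM. Hand1 had 668 and 905 CPM. The prolactin family members that mark mature giant cells had too few UMIs or were not analysed here.

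Among the genes ranked by size alone, the largest ratios included Plac1 (0.628 and 199 CPM), Pparg (2 and 1540 UMIs) and Gjb2 (1 and 1073 UMIs). Pparg encodes a nuclear receptor needed for the placental labyrinth, and Gjb2 a gap junction protein. The ratios of Pparg and Gjb2 rested on so few UMIs at 0 h that their intervals were wide, 9.23 [7.70, 12.60] and 9.45 [7.55, 15.33]. Nrk, encoding a placental kinase, had 60.6 and 844 CPM, and the epithelial ETS factor gene Elf3 had 10.8 and 197 CPM. At the other end stood Mmp9 and Spry4, then Nat8l (571 and 12.0 CPM) and Cyp26a1, which encodes an enzyme that degrades retinoic acid (194 and 1.02 CPM). The neural and pluripotency-associated factor genes Sox3 (1129 and 1 UMIs, -9.59 [-15.48, -7.70]) and Zic2 (1146 and 10 UMIs) were among them. The nuclear receptor gene Nr0b1 had 239 and 9.38 CPM, and the receptor gene Fgfr4 had 117 and 2.75 CPM. The NADPH oxidase gene Duox2 had 1275 and 4 UMIs, and its maturation factor gene Duoxa2 had 742 and 1, with a log2 ratio of -8.99 [-14.88, -7.09].

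Other signalling lists differed less. The TGF-beta and nodal response list had a median of -1.01 [-1.11, -0.93], at percentile 0.12, with 6 of 8 members lower. Smad7, an inhibitory SMAD, had 393 and 120 CPM. Lefty1, a nodal antagonist, had 8 UMIs at 0 h and 5 at 48 h, too few for a comparison. The BMP response list had a median of -0.76 [-0.90, -0.64]. The WNT list median was -0.66 [-0.93, -0.14] at percentile 3.2 over 5 members, but 0.62 when members from 1 UMI on were counted, and the YAP and TEAD list median was 0.19 [0.12, 0.27] at percentile 72.9. Among proliferation genes, the S phase list median was -0.03 [-0.08, 0.02] over 40 members and the G2 and M phase list median 0.03 [0.01, 0.07] over 50. Summed per thinned well, S phase UMIs had a median of 97 at 0 h and 81 at 48 h. Of the 48 h wells, 74 of 299 (24.7%) lay above the 0 h median. The sum gives most weight to abundant members, and 34 of the 40 members differed by less than 1.5-fold. The member Rrm2, a ribonucleotide reductase subunit gene, had 1054 and 452 CPM. The lower sum therefore does not show a general fall of the list. Mki67 had 188 and 249 CPM.

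Among metabolic and stress genes, the hypoxia and glycolysis list stood out, with a median of 1.08 [0.98, 1.17] at percentile 100 and 12 of 16 members higher. Ndrg1, a hypoxia-induced gene, had 32.4 and 432 CPM, Bnip3, a mitophagy receptor gene, 72.3 and 375 CPM, and the glucose transporter gene Slc2a3 319.7 and 1192 CPM. The imprinted list median was 0.67 [0.63, 0.72], at percentile 100, with Phlda2 and Ascl2 on the higher side and Mest (89.4 and 7.85 CPM) on the lower. The epithelial list median was 0.31 [0.21, 0.40], with 3 of 11 members higher, Krt8 and Esrp1 (1.49 on the log2 scale) among them, and 2 lower, including Epcam (239 and 133 CPM). The mesenchymal list median was -0.12 [-0.50, 0.07], with Twist1 (47.2 and 8.56 CPM) and Vim (281 and 172 CPM) lower. The p53 target list stood at 0.08 [-0.04, 0.15], cholesterol synthesis at -0.07 [-0.12, -0.02] and endocycle genes at -0.11 [-0.15, -0.06]. Immediate early and heat shock genes stood at 0.27 [0.13, 0.43]. The integrated stress response list had a median of 0.17 [-0.05, 0.32] and a mean of -0.04, with Vldlr (3.56 and 23.2 CPM) higher and the asparagine synthetase gene Asns (578 and 239.6 CPM) lower.

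Several markers of other lineages were expressed in these cells from the start. The epiblast and embryonic stem cell list had a median of -0.03 [-0.34, 0.10]. Its member Utf1 had 1271 CPM at 0 h and a log2 ratio of -1.67, Dppa4 475 and 153 CPM, and Klf4 8.06 and 17.2 CPM. In the primitive endoderm list, 6 of 8 members were lower, with a mean of -1.48, and the median lay at percentile 0 with a counting interval of [-2.27, -1.58]. Gata4 had 22.1 and 6.11 CPM, Gata6 6.17 and 1.12 CPM, and Pdgfra 3.14 and 13.1 CPM. Only 3 fibroblast genes could be compared, with a median of 0.93 [-0.12, 1.99]. Sparc (2483 and 1122 CPM) and Col1a1 (1.15 and 2.24 CPM), markers of endoderm and fibroblasts, were chosen after their values were seen.

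At 36 h, also on the first flow cell, the FGF, stem cell and trophoblast lineage lists differed from 0 h in the same direction as at 48 h, and both comparisons share the 0 h library. Of 9988 genes, 552 were at least 2-fold higher and 681 lower. The FGF and ERK list stood at -3.47 [-3.69, -3.30] and the stem cell list at -2.23 [-2.33, -1.90]. The syncytiotrophoblast list stood at 1.89 [1.35, 2.28], the ectoplacental cone list at 1.57 [1.46, 1.76] and the trophectoderm list at 0.90 [0.85, 1.24]. The sum of syncytiotrophoblast UMIs per thinned well did not follow the median over members: it had a median of 13 at 0 h and 11 at 36 h, with 102 of 307 wells at 36 h (33.2%) above the 0 h median. Other lists differed from the 48 h picture: immediate early and heat shock genes stood at -0.17 [-0.25, -0.11], the integrated stress response at -0.30 [-0.44, -0.08], the epiblast list at -0.74 [-0.85, -0.64] and 2 fibroblast genes at -0.14 [-0.80, 0.59]. Median and mean differed in sign for the giant cell list (0.72 and -0.70) and the WNT list (-0.33 and 0.46). Ascl2 had 425 CPM at 36 h, close to its 48 h level, while Syna had 4.40 CPM, Dlx3 57.5 CPM and Cdkn1c 195 CPM, all well under their 48 h levels.

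**Figure D1:**
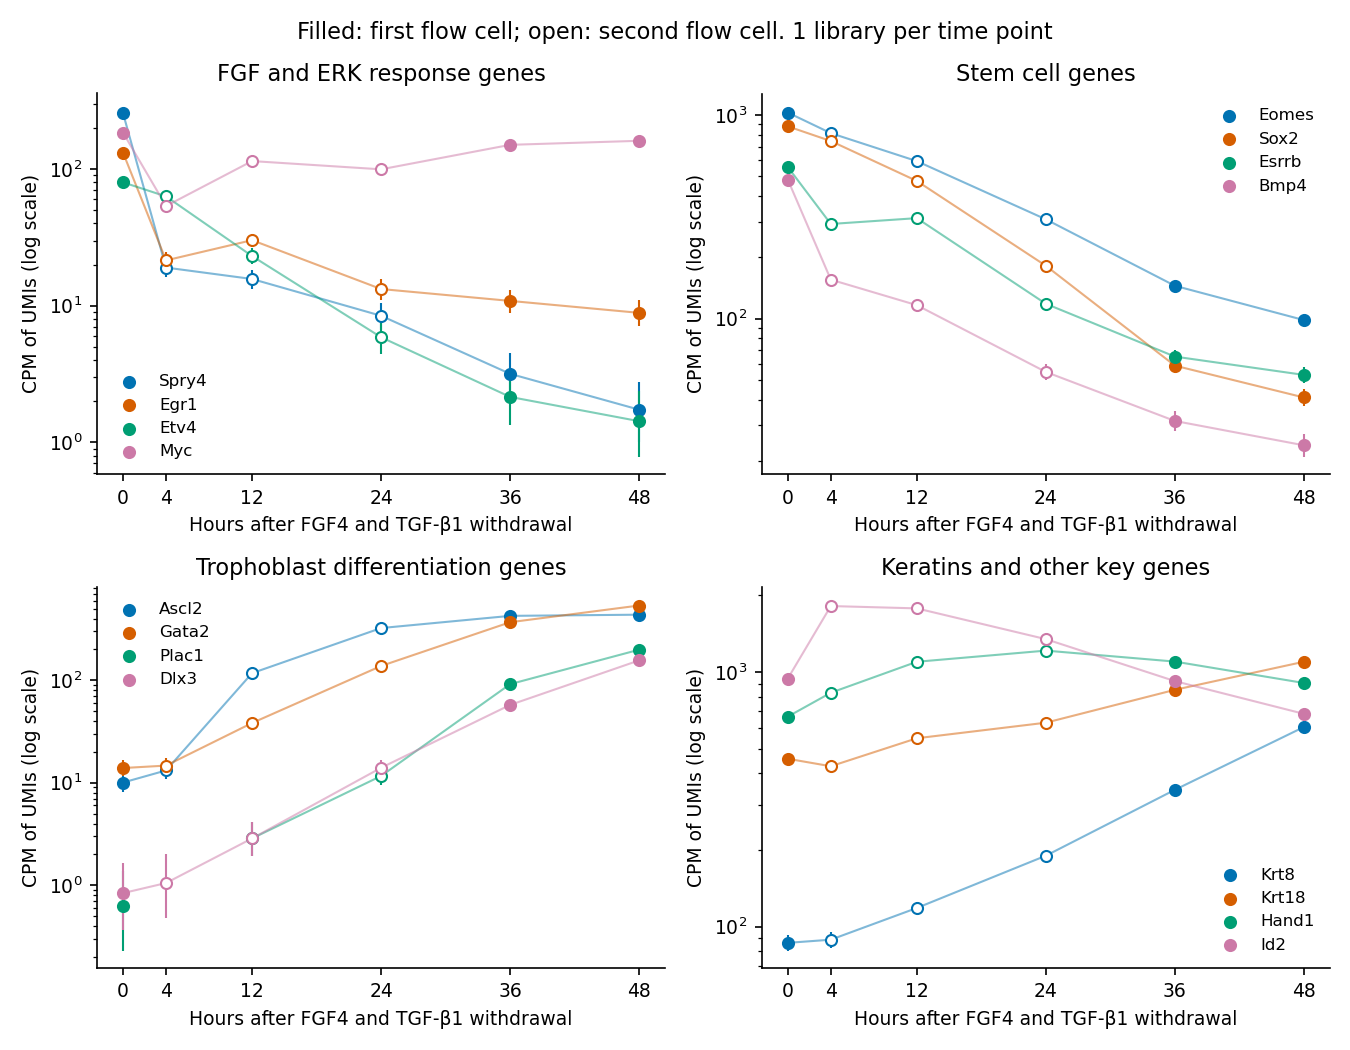
CPM of UMIs (log axis) against hours after withdrawal for 16 genes in 4 groups, 1 library per time point, with exact Poisson 95% intervals; filled points are on the first flow cell and open points on the second, and a library with 0 UMIs has no point. Egr1 stands at 21.5 CPM by 4 h, whereas Eomes still has 815 CPM at 4 h and reaches 98.3 CPM at 48 h.

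The comparison of 24 h with 4 h, within the second flow cell and with no library in common with 48 h against 0 h, described the middle of the course. Of 9787 genes, 256 were at least 2-fold higher and 389 lower. With TMM factors, 29.4% of these calls were on the higher side instead of 39.7%. The stem cell list had a median of -1.07 [-1.17, -0.95] and the FGF and ERK list -1.75 [-1.88, -1.61], with 9 of 13 and 12 of 14 members lower. Sox2 had 746 CPM at 4 h and 182 CPM at 24 h, and Etv4 had 63.1 and 5.88 CPM. Ascl2 led the higher genes with 13.2 and 323 CPM, followed by the erythroid and trophoblast factor gene Gata1 (7.70 and 98.7 CPM) and Gata2 (14.7 and 138 CPM). Phlda2 had 223 and 1166 CPM. On the lower side, Foxq1, a forkhead factor gene, had 74.0 and 1.18 CPM, and Slc30a3, a zinc transporter gene, 53.7 and 2.24 CPM. The ectoplacental cone list reached 1.03 [0.89, 1.20], the syncytiotrophoblast list only 0.44 [0.32, 0.71], and -0.11 over members with at least 100 UMIs. Summed syncytiotrophoblast UMIs per thinned well went the other way, with a median of 14 at 4 h and 13 at 24 h. The hypoxia and glycolysis list was at 0.52 [0.41, 0.61]. The giant cell list had a median of 0.23 and a mean of -0.60. The p53 target list was at -0.50 [-0.58, -0.38], at percentile 0.1. In the BMP list, with a median of -0.99 [-1.10, -0.89] and a mean of 0.01, Id1 went the other way with 7.23 and 39.4 CPM.

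Across 9692 genes the log2 ratios of 48 h against 0 h and of 24 h against 4 h had a Pearson correlation of 0.807 and a Spearman correlation of 0.669. Genes are not independent replicates, so this describes the 4 libraries. At least 2-fold higher in both were 208 genes, where independent lists would share 16.9, and lower in both were 319, where they would share 27.7. Only 3 genes were 2-fold higher in one and lower in the other.

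**Figure D2:**
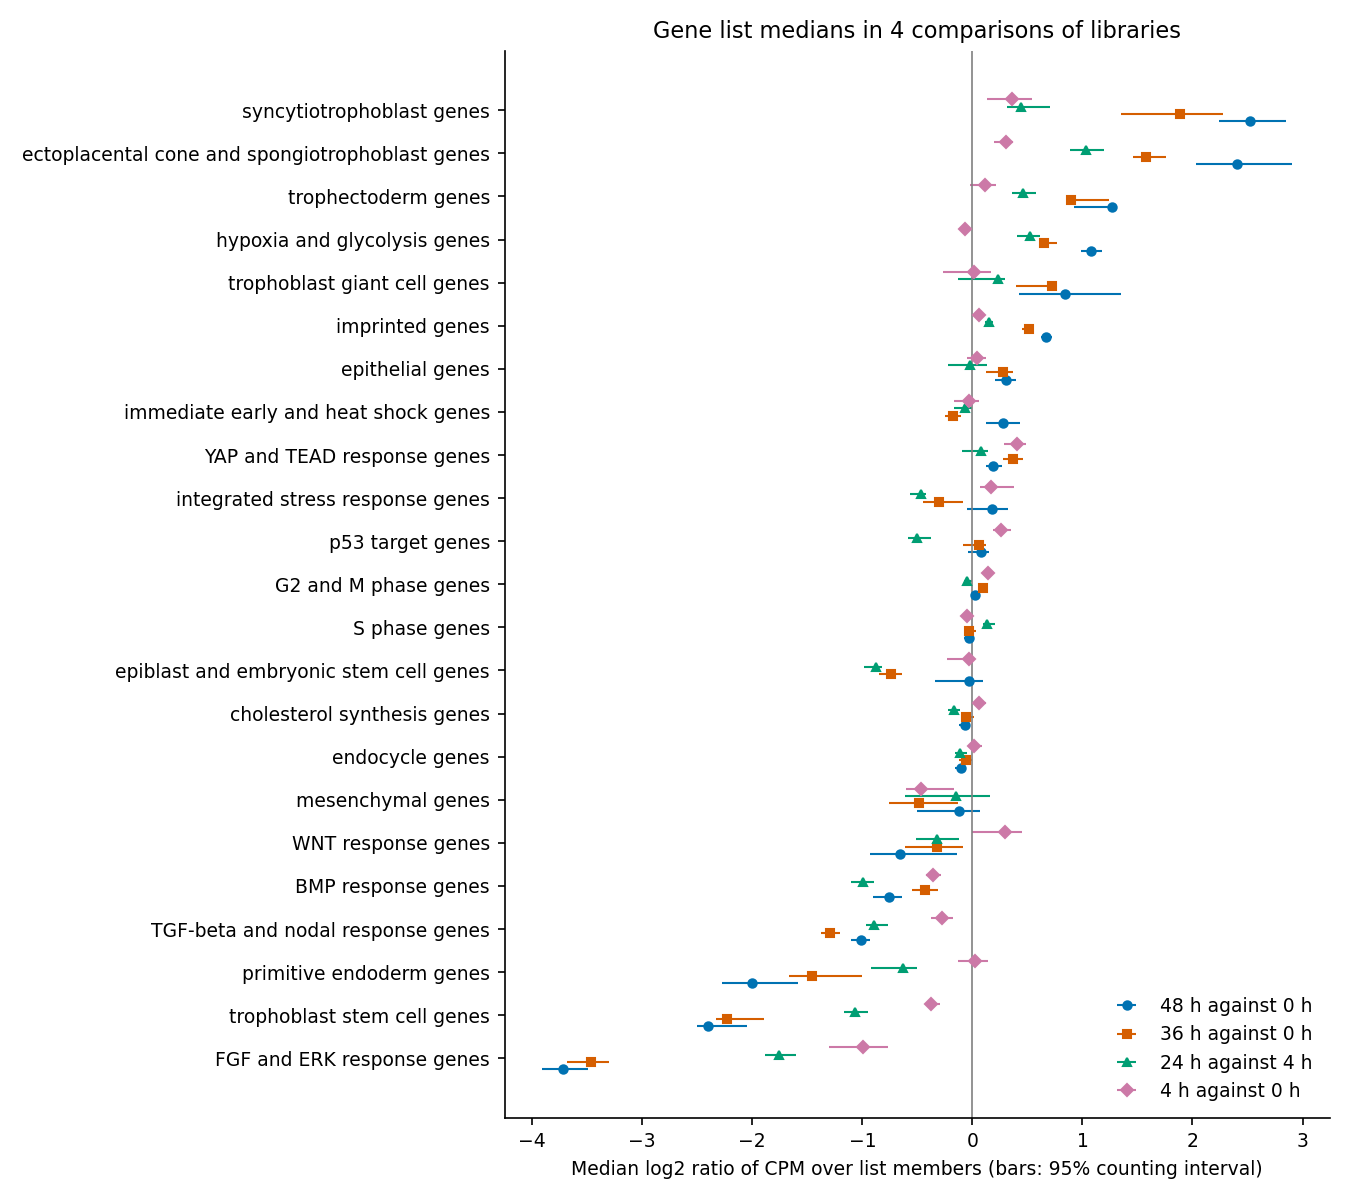
Median log2 ratio of CPM over the members of each fixed gene list with at least 5 measured members, for 4 comparisons of libraries; bars are 95% counting intervals. The FGF and ERK list lies lowest in all 4, from -0.99 for 4 h against 0 h to -3.72 for 48 h against 0 h.

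The 4 h library was set beside 0 h to see which genes differed first, although flow cell differed along with time. Of 9758 genes, 30 were at least 2-fold higher and 38 lower, and with TMM factors 36 and 35. The 38 lower genes had a median of -1.25. It was -0.22 for 36 h against 24 h, where the flow cell changes back. For 36 h against 0 h, on 1 flow cell, it was -2.42, but that ratio reuses the 0 h library that picked the genes. The lower genes included targets of growth factor signalling: Spry4 (2456 and 163 UMIs, -3.75 [-3.99, -3.53]), Egr1 (132 and 21.5 CPM), Junb (199.8 and 39.7 CPM), Spry2 (145 and 36.3 CPM) and Myc (185 and 53.7 CPM). The FGF and ERK list had a median of -0.99 [-1.30, -0.77], with 9 of 14 members lower and 0 higher. The immediate early and heat shock list stood near 0, with 2 of 10 members lower and a median of -0.03 [-0.17, 0.06] at percentile 40.4. Etv4, in contrast, had 80.0 CPM at 0 h and 63.1 CPM at 4 h, and 23.1 CPM at 12 h. Bmp4 had 482 and 155 CPM and Esrrb 556 and 292 CPM, while Eomes, Sox2 and Elf5 stood at 815, 746 and 317 CPM at 4 h. The stem cell list median was -0.37 [-0.43, -0.30], at percentile 0, with 4 of 13 members lower. Id2, an inhibitor of bHLH factors, had 942 and 1815 CPM. Other higher genes were Rhof (29.2 and 75.7 CPM), the stress-induced Gadd45b (21.7 and 49.4 CPM), Mycn (122 and 247 CPM) and Txnip (72.8 and 144 CPM). Serpine1, a TGF-beta target, had 172 and 67.3 CPM. In the TGF-beta and nodal list 1 of 7 members was lower and 6 differed by less than 1.5-fold, with a median of -0.28 [-0.37, -0.17]. The YAP and TEAD list median was 0.40 [0.29, 0.49], at percentile 100, with Amotl2 (315 and 491 CPM) and Ccn2 (a log2 ratio of 0.66) higher. The p53 target list was at 0.26 [0.19, 0.35] and the G2 and M phase list at 0.14 [0.11, 0.17], both at percentile 100. Median and mean differed in sign for the giant cell, epiblast and primitive endoderm lists, with medians of 0.01, -0.03 and 0.02 and means of -0.08, 0.17 and -0.03.

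Levels within a flow cell ordered as follows. Myc had 53.7, 115 and 99.7 CPM at 4, 12 and 24 h, and 185, 151 and 161 CPM at 0, 36 and 48 h. Id2 had 1815, 1777 and 1346 CPM at 4, 12 and 24 h, and 942, 921 and 685 CPM at 0, 36 and 48 h. Fgfr2, the receptor that binds FGF4 in these cells, had 288, 437 and 399.7 CPM on the second flow cell and 247, 309 and 227 CPM on the first.

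Counted per well after thinning, a UMI of Eomes was seen in 100% [98.9, 100] of 0 h wells and 42.8% [37.1, 48.6] of 48 h wells, and without thinning in 99.7% and 49.4%. For Sox2 the shares were 99.7% and 25.1% [20.3, 30.4], unthinned 99.7% and 31.8%. Spry4 was seen in 86.7% [82.5, 90.2] of wells at 0 h, 19.3% [14.8, 24.4] at 4 h and in 3 of 299 wells at 48 h, or [0.207, 2.90]%, unthinned 91.7%, 24.9% and 2.42%. Ascl2 was seen in 13.6% [10.1, 17.9] of wells at 0 h, 61.6% at 12 h and 79.9% [74.9, 84.3] at 48 h, unthinned 19.3%, 71.5% and 89.7%. Gata2 was seen in 14.6% and 76.3%, unthinned 22.9% and 88.8%. Dlx3 was seen in 1.86% [0.685, 4.00] of wells at 0 h and 53.5% [47.7, 59.3] at 48 h, unthinned 1.93% and 63.9%. Mki67 was seen in 89.5% of wells at 0 h and 90.3% at 48 h, unthinned 92.6% and 92.1%. The shares at 4 and 12 h differ from the others in flow cell as well as time.

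Wells of the 0 h library differed from each other beyond counting noise. Over 8069 genes the median variance over mean was 1.15, and 148 genes reached 2 times the trend, a number that was 320 when wells were thinned to 31000 UMIs. The largest excess was in the alcohol dehydrogenase gene Adh1 (variance over mean 16.2), then Mmp9 (14.8), Hand1 (15.2) and the mitochondrial ribosomal RNA mt-Rnr2 (13.6). Ly6a, Emp1, Igf2, mt-Rnr1, Mal, Peg10, Lgals9, Id2, Sp7, Mt2 and Sox3 completed the 15. Of these 15 genes, 5 were at least 2-fold lower at 48 h and 2 at least 2-fold higher. Among key genes of the stem cell state, variance over mean was 3.14 times the trend for Bmp4, 2.51 for Sox2, 1.74 for Elf5, 1.66 for Eomes, 1.46 for Esrrb and 1.02 for Tfap2c. Among the pairs of key genes, 43 of 171 correlations lay outside the shuffled 95% range, beside 8.55 expected by chance. Bmp4 and Spry4 had a Spearman correlation of 0.39, Eomes and Bmp4 0.33, and Id2 and Spry4 -0.37. The shuffled 95% range was about -0.11 to 0.11. By list, FGF and ERK UMIs correlated at 0.28 with stem cell UMIs and at -0.35 with trophectoderm UMIs. Stem cell and ectoplacental cone UMIs gave 0.02. Id2 alone had a mean of 14.5 of the 31.5 trophectoderm UMIs per thinned 0 h well, so the list value may largely repeat Id2 with Spry4. FGF and ERK with trophectoderm UMIs gave -0.32 at 4 h and -0.18 at 12 h. The later values were -0.10 at 24 h, 0.20 at 36 h and 0.02 at 48 h.

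At 48 h the wells were less alike: 450 of 8271 genes reached 2 times the trend. The ectoplacental cone list had a variance over mean of 51.2, against 3.26 at 0 h. Its means were 82.0 and 12.8 UMIs per thinned well, with standard deviations of 64.8 and 6.46. Phlda2 had a mean of 36.7 and Nrk of 13.5 of these UMIs at 48 h, against 2.90 and 0.969 at 0 h. Their own variances over mean at 48 h were 28.1 and 23.8, so the list value may largely repeat these genes. The syncytiotrophoblast list had a variance over mean of 17.2, against 1.89, with means of 20.7 and 13.2. Variance over mean rises with the mean at a fixed relative spread, so part of these differences goes with the level. The 10% of 48 h wells with most held 33.5% of the syncytiotrophoblast UMIs, against 17.7% at 0 h. For the giant cell list the same share was already 30.8% at 0 h. Hand1 had a mean of 11.1 and Mmp9 of 5.21 of the 19.4 giant cell UMIs per thinned 0 h well. Both were among the genes with the largest excess variance at 0 h, so the share may largely repeat them. Krt8 and Krt18 correlated at 0.81 across wells, Krt8 and Id2 at -0.64, Krt8 and Eomes at -0.56, and Eomes and Esrrb at 0.54. Krt8 and Cdkn1c gave 0.61. Shuffled values stayed within about -0.11 and 0.12. The stem score was stem list UMIs minus ectoplacental cone and giant cell list UMIs per thinned well. At 48 h it therefore also gives much weight to Phlda2 and Nrk. On the first flow cell it had a median of 48 at 0 h, -43 at 36 h and -60 at 48 h. On the second the median was 30 at 4 h, 9 at 12 h and -18.5 at 24 h. The share of wells above the 0 h median was 15.7% [11.7, 20.5] at 4 h and 9.38% [6.41, 13.1] at 12 h. At 24 h it was 1 of 310 wells, and at 48 h 0 of 299, which allows up to 1.23%. The shares at 4, 12 and 24 h differ from 0 h in flow cell as well as time. The score is a range and not a cell type.

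**Figure D3:**
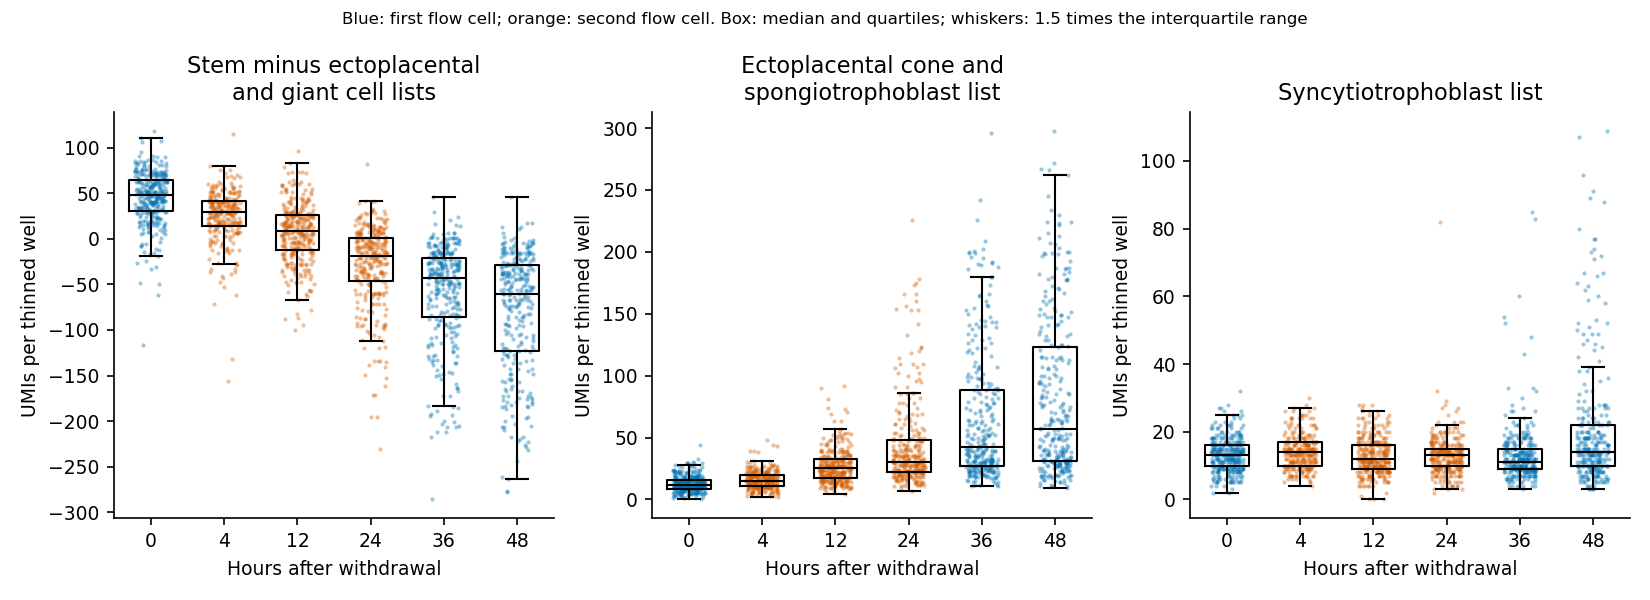
UMIs per thinned well (15500 UMIs) for the stem score and for 2 gene lists, against hours after withdrawal; points are wells, boxes medians and quartiles, blue the first flow cell and orange the second. The median of the stem score runs from 48 at 0 h to -60 at 48 h, and syncytiotrophoblast UMIs are most spread out at 48 h, where their median is 14.

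Clustering of all wells gave 6 clusters of 94 to 707 wells, and the 0 h library alone gave 4. No cluster had 3 markers of a fixed type among its top 10 genes, so all stay unnamed. Summed over their members, epiblast markers had 628 to 2111 CPM across the clusters of both runs. Primitive endoderm markers had 288 to 3819 CPM and fibroblast markers 5.25 to 11.2 CPM. These sums give most weight to abundant members, such as Utf1 among epiblast and Sparc among endoderm markers. They do not show that whole marker sets were expressed. In the all-well run, the cluster of 301 wells had 1 trophectoderm, 1 ectoplacental cone and 1 syncytiotrophoblast marker among its top 10 genes. The cluster of 94 wells, 73.4% of them from 48 h, had 1 ectoplacental cone and 1 syncytiotrophoblast marker. That of 481 wells had 1 trophectoderm marker and that of 707 wells 1 giant cell marker. In the run on the 0 h library, the cluster of 77 wells had 1 primitive endoderm marker.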

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

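The alternative with wells of at least 20000 UMIs was chosen after the data had been seen; the other alternatives were planned. Of 958 list medians recomputed, 821 stayed within the counting interval of the reported value. The sign changed in 46, and in 4 of these the reported median had been at least 1.5-fold from 0 change with an interval off 0. Of 994 ratios of named genes, 905 stayed and 89 left the interval; the sign changed in 2, both of Krt8 at 4 h, which was near 0. Shares of wells with a UMI depended on depth: 114 of 300 stayed and 186 moved, since more UMIs per well raise such a share. Well minimums of 1000 and 4000 UMIs and the use of all barcodes removed no well, tested nothing and are left out of these numbers. Without a minimum of UMIs, genes of a few counts entered and gene numbers grew to 5213 higher and 3859 lower for 48 h against 0 h, 4429 and 3804 for 36 h, 3549 and 3391 for 24 h against 4 h, and 2709 and 2871 for 4 h against 0 h. Under the other alternatives these 8 counts stayed within 1.5 times the reported ones. With the mean in place of the median, the stem cell list gave -2.04, -1.81 and -0.81 for 48 h, 36 h and 24 h, and the FGF and ERK list -1.31 for 4 h. With members from 1 UMI on, the stem cell list gave -1.19 for 24 h. Without the 5% of wells with most UMIs the FGF and ERK list gave -1.93 for 24 h, and in wells of at least 20000 UMIs the stem cell list gave -0.45 for 4 h. The 4 were the giant cell list with the mean (-0.0707 at 48 h, -0.70 at 36 h), the BMP list with the mean (0.00882 for 24 h), and the WNT list with members from 1 UMI on (0.62 at 48 h). The mean changed 9 signs in all, among them the giant cell list for 24 h (-0.60), the WNT list at 36 h (0.46) and the integrated stress list at 48 h (-0.04). Members with at least 100 UMIs changed 8, with the syncytiotrophoblast list for 24 h at -0.11, and the TMM and DESeq2 factors 4 each. Of 34 other results, on rankings, scores, variance and clusters, 27 stayed and 7 moved. Thinning to 31000 UMIs moved 4, with 320 genes over the variance trend at 0 h in place of 148. Adding 1 CPM in place of 5 CPM moved 2 of 6 counts of named genes kept in the rankings. Resolution 1.0 gave 11 clusters in place of 6. Apart from the added low counts and the share of wells, the cause was not tested.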

Other observations

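The tests on the 4 h genes, the 48 h wells, the near-zero genes, Cdx2 and the number of X-linked genes were chosen after the results were seen; those on the 0 h axis, the cell cycle and X dosage were written before theirs were.

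Within the 48 h library, some genes of trophoblast differentiation went together from well to well. Dlx3 correlated with Pparg at 0.71, with Plac1 at 0.63 and with Gata2 at 0.60, whereas Hand1, a giant cell regulator, correlated with Gata2 at -0.62 and with Dlx3 at -0.52. Eomes and Gata2 gave -0.52. Among pairs of the fixed key genes, Hand1 correlated with Id2 at 0.54, and Id2 with Eomes at 0.55. Hand1 was already seen in 97.2% of thinned 0 h wells. Its negative values with Gata2 and Dlx3 therefore do not show a giant cell branch. By list, trophectoderm UMIs correlated at 0.60 with ectoplacental cone UMIs and at -0.42 with G2 and M phase UMIs. At 0 h, Spry4 correlated with Sox3 at 0.39 and with Cyp26a1 at 0.37. These gene pairs, unlike the lists and the pairs of fixed key genes, were chosen after the clusters had been seen. The files used held no second library of either time. At 36 h Dlx3 gave 0.54 with Pparg, 0.56 with Plac1, 0.51 with Gata2 and -0.35 with Hand1. At 24 h it gave 0.42 with Gata2 and -0.09, inside the shuffled range, with Hand1. At 4 h Spry4 gave 0.16 with Sox3 and 0.18 with Cyp26a1.

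The 38 genes at least 2-fold lower at 4 h than at 0 h, Spry4 and Egr1 among them, had a median log2 ratio of -1.25, and the 2 libraries differed in flow cell as well as time. If the flow cell alone had lowered them, the same genes would be higher by a similar amount at 36 h than at 24 h, where the flow cell changes back. Their median there was -0.215 (-0.46 to -0.0446 on resampling genes, -0.374 to -0.0847 by counting), not above 0.623, which is 0.5 times the size of the drop, and 2 of the 38 were higher by that much. At 36 h against 0 h, on 1 flow cell, their median was -2.42, and at 12 h against 4 h it was -0.0524. Both of these ratios reuse a library that picked the genes. High values peculiar to the 0 h library would lower 36 h against 0 h too, so the -2.42 is not separate evidence. A response to withdrawal is a hypothesis that remains open, and the share of the 4 h difference due to the flow cell cannot be separated for single genes.

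Wells of the 48 h library differed in syncytiotrophoblast UMIs with a variance over mean of 17.2, where counting noise gives 1. Each well had been thinned to the same depth, at which the list gave 1.89 at 0 h and 1.74 at 4 h, so unequal depth of the wells did not produce the spread. A split among cells of this culture may underlie it, as a hypothesis, but doublets and position on the plate stay open.

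Of 93 S, G2 and M phase genes, with a median of 146 CPM, 3 stayed under 1 CPM in each library: Cdc45 and Kif11 with 1 UMI each and Nek2 with 3 UMIs over all 6 libraries. Dividing cells need these genes, so reads not assigned to a gene are a candidate cause. Cdx2, with 42 UMIs at 0 h beside 9838 for Eomes, may share this cause or be truly low, and these counts cannot tell which.

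One hypothesis was that wells at 0 h were already ordered along the later change. UMIs of the 256 genes higher and the 389 genes lower at 24 h than at 4 h had a Spearman correlation of -0.541 across the 323 thinned 0 h wells, where random gene sets matched on expression gave -0.187 to 0.103 and reached -0.297 at the lowest. After regression on S phase and G2 and M phase UMIs it was -0.591, with random sets at -0.179 to 0.101, so cell cycle stage did not account for it. Without the 10 most abundant genes of each set it was -0.477, and at 4 and 12 h it was -0.624 and -0.747. No random sets were drawn for these last values, and the 4 h library is among those that picked the genes. Going by the full sets at 0 h, some cells may be further along before withdrawal. Random sets are not co-regulated, however, which makes them a weak null. Any 2 opposed programmes of these cells could give the same sign.

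A second hypothesis concerned the X chromosome, since 7 of the 15 named genes with the largest increases at 48 h, such as Plac1 and Nrk, are X-linked. Of the 826 genes at least 2-fold higher, 61 were X-linked, where random draws matched on expression gave a median of 28 (19 to 39) and at most 50. For 24 h against 4 h, which shares no library, 21 were X-linked beside 9 (4 to 15, at most 22). Among the 745 lower genes 32 were, beside 25 (17 to 35). The median log2 ratio of 336 X-linked genes, 0.167, exceeded that of 9557 autosomal ones, 0.0747, by 0.0922. This is far below what a change in dosage of the whole chromosome in most wells would give. The ratios pool UMIs over wells, so such a change in a small share of wells was not tested. The excess may lie in a subset of X-linked trophoblast genes, which stays a hypothesis.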
